A study of Gallus gallus with 6 samples.

How the data were processed

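RNA-seq libraries from the abdominal fat of male broilers were analysed, 3 from the thermoneutral and 3 from the heat stress group. Per the labels' protocols the chickens moved to individual cages on day 14, the room temperatures were 22 and 32 °C (each ± 0.5 °C) at 50% humidity with light for 24 h a day, and total RNA was extracted with TRIzol and made into libraries with a stranded, poly(A)-selecting kit. Titles put each library in its group and number it. Nothing in the labels states that each library is 1 chicken, although library names carry different numbers, so p-values measure the spread between these libraries. No sequencing batch or date is given in the sources used here.

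Per the submitters' processing notes the tools were HISAT2 2.1.0, Bowtie2 2.3.4.1 and StringTie 2.1.3b and the genome build GRCg6a; their roles, and whether counting used strand, are not given in the sources used here. Genes that overlap an antisense partner therefore carry reads that cannot be assigned with certainty, as do members of families of near-identical copies. Per the file headers the authors deposited raw read counts per gene, and the values were whole numbers with different totals per library. Per the file headers the same table also holds the authors' FPKM values and TPM values, which are scaled for gene length and depth and were used only in alternatives. Signed fold changes (ratios of heat stress over thermoneutral, negative when lower) and raw and adjusted p-values came from the authors' deposited tables, per the file headers. DESeq2 with default settings on all listed genes gave the same number of genes at an adjusted p under 0.05 (1364) and log2 fold changes within 6.63e-05 of the authors' values. The authors' deposited adjusted p was blank for 630 genes. A deposited table of gene ontology terms holds the authors' adjusted p-values and counts of genes per term. Its companion of genes per term was not used here. The tables hold 30 further columns of values per library that were left unused, 12 of normalized values of unstated method and 18 under the same measure names in the authors' shorter list. The lowest count in the table is 1, so a gene with 0 counts in any library is not listed, and genes switched on or off between the groups cannot be seen. Coordinates are not printed, since the reference gene table at hand is of another build (GRCg7b). It was used only to find current symbols, and 14044 of 15491 gene IDs matched. Symbols that were placeholders or repeated (50) were kept apart by gene ID.

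Total counts per library ran from 30673333 to 45163458. The 10 most abundant genes took 12.2% to 13.2% of counts in thermoneutral libraries and 9.53% to 10.02% in heat stress libraries. Log2 CPM correlated at 0.968 to 0.984 within groups and 0.952 to 0.975 between groups, across genes, which are not independent replicates. Counts of any 2 libraries of a group differed far beyond sampling noise (chi-square per degree of freedom 36.1 to 103.3), so none was treated as a copy of another.

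Genes were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test on the deposited counts with TMM scaling and filterByExpr, group as the only term, and Benjamini-Hochberg adjustment at an FDR of 0.05. The standard error is the absolute log2 fold change divided by the square root of F. CPM values use the library totals of tested genes scaled by TMM, and are given as mean ± SD over 3 libraries. A second threshold took an absolute log2 fold change of at least 1 with an unadjusted p under 0.05. With 3 libraries against 3, an exact permutation test of a single value cannot go below p = 0.1, so only models fitted across genes were used.

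Before the data were examined, 25 lists of process genes and 14 lists of cell type and neighbouring tissue markers were written down. The tests, the alternatives and the rule for genes to name were written down with them. The lists hold 1518 different symbols, 1209 of them matched to a listed gene. Of the 1191 genes tested in these lists, 61 are in 2 or more lists. Lists with at least 5 tested genes were compared with all other genes by camera in limma 3.58.1 on voom values, two-sided, with a preset correlation between genes of 0.01 and adjustment over the lists of a kind. Camera with an estimated correlation and fry stand beside it. With an estimated correlation 0 of the 15 lists past camera held. Camera at the preset correlation also passed lists of both kinds in every regrouping of the libraries that mixed the groups. Members were also adjusted over the list alone. The rule named the 10 largest rises and 10 largest falls among genes past the FDR with a proper symbol, a mean of at least 1 CPM and no overlap between groups, filled to 10 by p where fewer passed. It added up to 4 members per process list past the FDR, or the 3 of smallest p, 3 members of smallest p for cell type lists past the test, and 12 genes of heat response and fat metabolism fixed by name. Other genes named were picked from list members after their values were seen.

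The pipeline was tested on simulated data: counts for 14743 genes with 200 genes changed, drawn 5 times from the libraries' own means, totals and dispersions. For this comparison edgeR recovered 48% of genes changed 2-fold and 81.8% of those changed 4-fold, with 4.7% of calls false, and DESeq2 1.42.0 recovered 66.4% and 87.6% with 26.5% false. A list shifted by -0.5 on the log2 scale was called in 5 of 5 draws and 0 of 190 unshifted lists were called. The simulated genes vary independently of one another, unlike real ones. Alternatives were DESeq2, limma-voom with and without library weights, other scalings and filters, limma on log2(FPKM or TPM + 1 or 0.1) for genes of at least 1 in at least 3 libraries, the library number as a block, and each library left out. Thinning all libraries to 30673333 counts and a haemoglobin covariate were added after seeing the data. Figures were drawn with matplotlib 3.10.9.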

Results

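Messenger RNA was sequenced from the abdominal fat of male Ross broilers, a fast-growing meat-type chicken, in 6 libraries, 3 for each of the 2 groups. The thermoneutral group stayed at 22 °C and the heat stress group lived at 32 °C from day 21 to day 35 of age. Total counts per library were 30673333, 30825771 and 35836632 in the thermoneutral group and 43110561, 45163458 and 38336086 in the heat stress group, so depth did not overlap between the groups. Levels are in CPM, counts per 1e+06 of a library's TMM-scaled total, and 1 CPM was 29.98 counts in thermoneutral 1, the smallest library. The deposited table listed 15491 genes, each with at least 1 count in every library, and 14743 passed the filter on low counts. The first principal component held 38.21% of the variance of log2 CPM and ran from -53.3 in thermoneutral 2 to 36.8 in heat stress 1, with all 3 heat stress libraries above all 3 thermoneutral ones. The second component held 21.75% and crossed the groups. It put thermoneutral 2, heat stress 2 and heat stress 3 (-20.7, -33.8 and -16) apart from the other libraries (20.5 to 25.8). Mitochondrially encoded mRNA made up 6.78% to 7.86% of counts in thermoneutral fat and 6.02% to 6.43% in heat-stressed fat.

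The comparison addressed how chronic heat exposure changes gene expression in the fat of growing chickens. PLIN4, HPGD, FASN and CD3D were among the genes that differed. PLIN4 (gene ID 100857433), a coat protein of lipid droplets, averaged 155 ± 42.1 CPM in thermoneutral fat and 1140 ± 419 CPM in heat-stressed fat (SD, n = 3 each), a 7.35-fold rise. HPGD (gene ID 422567), the enzyme that inactivates prostaglandins, fell 3.49-fold, from 99.1 ± 8.93 to 28.4 ± 1.63 CPM. FASN (gene ID 396061), the fatty acid synthase, rose 1.93-fold, from 196 ± 23.6 to 379 ± 20.1 CPM. CD3D (gene ID 396518), a subunit of the T cell receptor complex, fell 1.70-fold, from 39.1 ± 2.22 to 23.0 ± 0.54 CPM.

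In all, 26 of the 14743 genes tested differed at an FDR of 0.05 in edgeR's quasi-likelihood test, 17 higher and 9 lower in heat stress. At an unadjusted p under 0.05 there were 2765 genes, against 737 expected by chance. The groups' values did not overlap for 25.01% of genes, where chance gives 10%. LOC101749734, a long noncoding RNA, rose 5.475-fold. Among genes past the FDR with a proper symbol, the largest rise after PLIN4 belonged to VWA1, a matrix protein (log2 fold change 2.03 ± 0.21 SE, FDR = 0.0368). TMEM246 (1.96 ± 0.24, FDR = 0.0476) and CNTFR, the receptor for ciliary neurotrophic factor (1.93 ± 0.21, FDR = 0.0415), came next. AKR1B10L4, of the aldo-keto reductase family, rose 2.65-fold. CCBE1, a secreted protein of lymphatic vessel growth, rose 2.53-fold with almost no spread in heat stress, from 35.5 ± 5.82 to 89.7 ± 3.19 CPM. TSPAN18 (a tetraspanin) and MECOM (a transcription factor) rose 2.36-fold and 1.75-fold.

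Among the 9 genes that fell, IL20RA, a receptor chain for interleukin-20 family cytokines, had the largest drop (6.28-fold lower, from 9.60 ± 1.57 to 1.52 ± 0.19 CPM, FDR = 0.0225). MOXD1, a copper-dependent monooxygenase, was 3.89-fold lower (FDR = 0.00413, as for HPGD). The matrix proteins THBS2 and PODN fell 2.76-fold and 1.76-fold. GPR34, a lysophospholipid receptor of myeloid cells, fell 1.93-fold. A T cell receptor beta segment (TRBV6-5) and an immunoglobulin heavy chain gene (IGHVL) fell 2.29-fold and 2.02-fold. These 2 genes and AKR1B10L4 belong to families of near-identical copies, so their values are uncertain. COL8A1, a short-chain collagen, stood just outside the threshold (log2 fold change -1.05 ± 0.13, FDR = 0.0513).

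**Figure D1:**
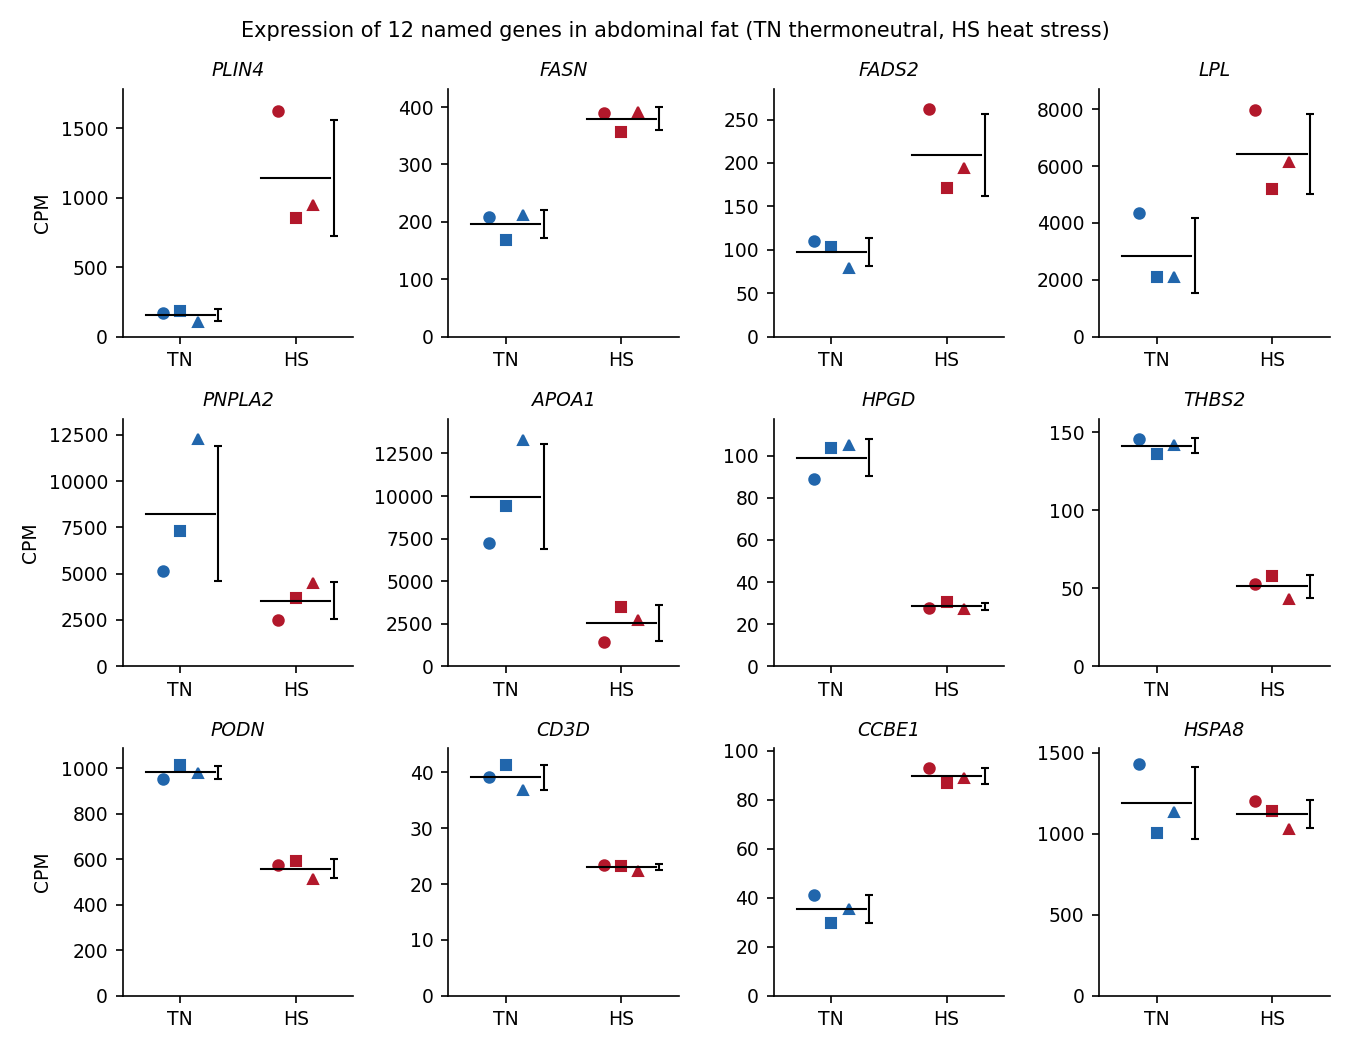
CPM (y axis, from 0) of 12 named genes in the 3 thermoneutral (TN, blue) and 3 heat stress (HS, red) libraries, where circles, squares and triangles are replicates 1, 2 and 3. Horizontal lines are group means and bars 1 SD. For HPGD, THBS2, CD3D and CCBE1 the groups stand far apart (HPGD 99.1 against 28.4 CPM), while HSPA8 overlaps (1189 against 1122 CPM).

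The number of genes called changed with the test and with other settings. DESeq2 called 1352 genes, the 26 among them. In simulated data 26.5% of its calls were false against 4.7% for edgeR. That simulation used edgeR's dispersions and 200 changed genes, and DESeq2 called 212.4 genes on average there. The false share among the 1352 calls is therefore not known. In edgeR, a filter of 1 CPM in all 6 libraries gave 133 genes, library totals in place of TMM gave 99, 80 higher and 19 lower, and the library number as a block gave 95. Leaving out 1 library gave 10 genes without thermoneutral 2 (5 higher), 3 without thermoneutral 3 (0 higher), 6 without heat stress 2 (3 higher) and 3 without heat stress 3 (0 higher). All 26 kept their direction, but their groups did not overlap in value, so leaving out 1 library could hardly turn a sign. FASN and CD3D passed the FDR in none of the fits with 1 library left out. PLIN4 passed only without heat stress 1 (FDR = 0.0467). On log2(TPM + 1) limma gave 223 higher and 27 lower, and on log2(FPKM + 1) 96 and 24.

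Genes of fatty acid synthesis were higher in heat-stressed fat. Of 33 measured members of this list, 6 rose and 0 fell when adjusted over the list alone, and 1 (FASN) passed over all genes. The other risers were the desaturases FADS1 (log2 fold change 0.64 ± 0.09) and FADS2 (1.10 ± 0.19, from 97.4 to 209 CPM), the transcription factor SREBF1 (25.9 ± 4.95 to 52.0 ± 7.99 CPM), the mitochondrial acetyl-CoA synthetase ACSS1 (0.63) and acetyl-CoA carboxylase ACACA (0.49 ± 0.13). The list's median was 0.20 (camera adjusted p = 0.00127, and adjusted p = 0.59 with an estimated correlation). On the voom values camera uses, it was 0.19 with all libraries and 0.13 without thermoneutral 2. SCD, the stearoyl-CoA desaturase, averaged 79.7 ± 112 CPM in thermoneutral fat and 457 ± 458 CPM in heat stress, and its FDR was 0.319.

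Triacylglycerol synthesis and lipid droplet genes split. Of 30 measured, 6 rose when adjusted over the list alone: PLIN4, GPAT3, the first acyltransferase of the pathway (2.55-fold), DGAT2, the last (log2 fold change 2.73 ± 0.58, 51.7 ± 13.7 to 342 ± 284 CPM, with 667, 143 and 215 CPM in heat stress 1, 2 and 3), PCK1 (3.85-fold, near 1 CPM), ACSL1 (1.33 ± 0.36) and glycerol kinase GK (0.57). LPIN1, a phosphatidate phosphatase, fell in that count (-1.48 ± 0.39). This list did not pass camera (median 0.11, adjusted p = 0.11, and adjusted p = 0.59 with an estimated correlation), but passed fry, which asks whether a list's genes move one way on balance (adjusted p = 0.0356), and passed camera without heat stress 1 (adjusted p = 0.0393). Lipolysis genes had 3 risers of 41 adjusted over the list alone: PNPLA3 (5.01-fold), the lipase inhibitor G0S2 (1.86-fold) and the adenylate cyclase ADCY5 (1.53-fold). PNPLA2, the main triacylglycerol lipase of fat, averaged 8237 ± 3648 and 3548 ± 1014 CPM, a log2 difference of -1.21 ± 0.36 that did not pass over all genes (FDR = 0.144). Lipolysis as a list did not pass (median 0.11, adjusted p = 0.51).

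Uptake of fatty acids and lipoproteins had 4 risers and 2 fallers of 23 adjusted over the list alone. The risers were the caveolae protein CAV1 (1.64-fold), the receptors VLDLR (1.63-fold) and LRP1 (log2 fold change 0.57), and lipoprotein lipase LPL (2852 ± 1304 to 6434 ± 1411 CPM). APOA1, the main protein of high-density lipoprotein, fell 3.92-fold in that count, from 9966 ± 3064 to 2544 ± 1057 CPM, as did ANGPTL5 (-0.99). The list as a whole did not pass (adjusted p = 0.78). Cholesterol synthesis passed upward (26 measured, median 0.23, adjusted p = 0.00367, and adjusted p = 0.59 with an estimated correlation). Its 2 risers adjusted over the list alone were INSIG1, a sterol-regulated brake on the pathway (log2 fold change 1.20 ± 0.17), and HSD17B7 (2.93-fold, with 36.8 ± 19.6 CPM in heat stress).

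Extracellular matrix genes were lower as a list (80 measured, median -0.19, adjusted p = 0.00614, and adjusted p = 0.86 with an estimated correlation). Adjusted over the list alone, 13 fell and 4 rose. THBS2, COL8A1 and SPON2 (2.32-fold) fell, as did the small proteoglycan LUM (1.64-fold), POSTN (periostin, 2852 ± 142 to 1627 ± 308 CPM), FBLN1 (-0.96 ± 0.24) and the collagen I chain COL1A2 (8813 ± 616 to 6088 ± 693 CPM). LOX, the collagen cross-linking oxidase, rose (log2 fold change 0.90 ± 0.19), along with MMP15, ACAN and the collagen chaperone SERPINH1. The preadipocyte and fibroblast list, 7 of whose genes are also in the matrix list, had a median of -0.33 (20 measured, 1 faller, LUM, adjusted over the list alone, adjusted p = 0.0183, and adjusted p = 0.56 with an estimated correlation). Its DPT and PDGFRB had log2 fold changes of -0.83 ± 0.22 and 0.32 ± 0.09. Without thermoneutral 3 or heat stress 3 this list no longer passed (adjusted p = 0.0635 and 0.0888, voom medians -0.27 and -0.24 against -0.36). Its mean log2 CPM relative to thermoneutral fat was -0.04 in heat stress 2 and -0.09 in thermoneutral 2, so the groups overlapped.

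T cell and NK cell markers were lower throughout. All 31 measured had negative log2 fold changes (median -0.61), 14 fell and 0 rose adjusted over the list alone, and 1 (CD3D) passed over all genes. CD3E fell from 63.4 ± 2.67 to 41.4 ± 3.004 CPM and the signalling adaptor TRAT1 from 12.1 ± 1.67 to 6.17 ± 0.34 CPM, and CD4 (-0.99 ± 0.23) and CD8A (-0.72 ± 0.20) fell too. The list score, the mean log2 CPM relative to thermoneutral fat, was -0.03, 0.03 and 0.01 in the 3 thermoneutral libraries and -0.47, -0.73 and -0.64 in the 3 heat stress libraries. Both tests passed (camera adjusted p = 1.29e-11, fry adjusted p = 0.00359), but camera gave adjusted p = 0.077 with an estimated correlation. Haemoglobin mRNA (HBA1 with HBBA) was 414, 812 and 357 CPM in thermoneutral fat and 193, 338 and 308 CPM in heat stress.

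Other immune cell lists were also lower. Macrophage and dendritic cell markers (31 measured, median -0.29) had 1 faller adjusted over the list alone, the dendritic cell receptor XCR1 (2.87-fold), with FLT3 and LY86 at log2 fold changes of -0.86 ± 0.24 and -0.88 ± 0.26. Their adjusted p was 0.000135, and adjusted p = 0.51 with an estimated correlation. The list score of heat stress 1 was -0.04, within 0.1 of the thermoneutral libraries, against -0.61 and -0.55 in heat stress 2 and 3, and the voom median was -0.33 with all libraries and -0.63 without heat stress 1. B cell and plasma cell markers (16 measured, median -1.45, adjusted p = 0.00033, and adjusted p = 0.51 with an estimated correlation) had 2 fallers in the same count, the transcription factor PAX5 (5.03 ± 4.47 to 0.37 ± 0.17 CPM) and CD79B (6.07 ± 5.41 to 0.999 ± 0.265 CPM), with CXCR5 at -2.21 ± 0.64. Thermoneutral 2 was the highest library for each of these 3 genes, and without it PAX5 stood at -2.74 (-3.76 with all libraries), CD79B at -1.57 and CXCR5 at -1.25. The B cell list's voom median went from -1.335 to -0.86 without thermoneutral 2 and to -2.001 without heat stress 1, whose list score was -0.52 against -1.75 and -1.62 in heat stress 2 and 3. Heterophil and thrombocyte markers (17 measured, 0 past in edgeR adjusted over the list alone, 2 at an unadjusted p under 0.05 and 2 in DESeq2, median -0.62, adjusted p = 0.0204) rested on thermoneutral 2: without it the adjusted p was 0.815 and the voom median 0.02, against -0.46 with all libraries. That median was -0.97, -0.86 and -0.72 without thermoneutral 1, thermoneutral 3 and heat stress 2, and turned to 0.33 with the haemoglobin gene HBBA as a covariate, a setting chosen after seeing the data (adjusted p = 0.472). HBBA did not overlap between the groups, so that fit cannot separate blood from treatment. With an estimated correlation the adjusted p of the heterophil list was 0.56. The members of smallest p were F13A1 (-1.22 ± 0.34), THBS1 (-0.84 ± 0.27) and S100A9 (-1.37 ± 0.63, and -0.26 without thermoneutral 2).

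Endothelial markers were higher, with 13 of 23 rising and 0 falling adjusted over the list alone (median 0.43, camera adjusted p = 1.23e-07, fry adjusted p = 0.0246, and camera adjusted p = 0.25 with an estimated correlation). Risers included the transcription factor SOX7 (1.95-fold), the growth factor receptors FLT1 (1.78-fold) and FLT4 (1.45-fold), and the apelin receptor APLNR (2.07-fold). Adipocyte markers passed upward (18 measured, median 0.60, adjusted p = 0.000103, and adjusted p = 0.42 with an estimated correlation), but members moved apart: 8 rose and 2 (PNPLA2 and LPIN1) fell adjusted over the list alone. Of the 18, 15 had positive and 3 negative log2 fold changes. All 18 are also in a process list. Abundant adipocyte mRNAs such as FABP4 (7565 ± 445 and 6238 ± 791 CPM), a fatty acid carrier, and the hormone ADIPOQ (338 ± 81.4 and 364 ± 48.9 CPM) did not pass. PPARG, the master regulator of adipocytes, averaged 227 ± 30.7 and 343 ± 148 CPM (FDR = 0.318). PLIN1 averaged 4258 ± 1325 and 6478 ± 994.5 CPM (FDR = 0.279). CEBPA averaged 109 ± 44.4 and 233 ± 83.8 CPM (FDR = 0.183), and neither of these last genes overlapped between the groups.

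**Figure D2:**
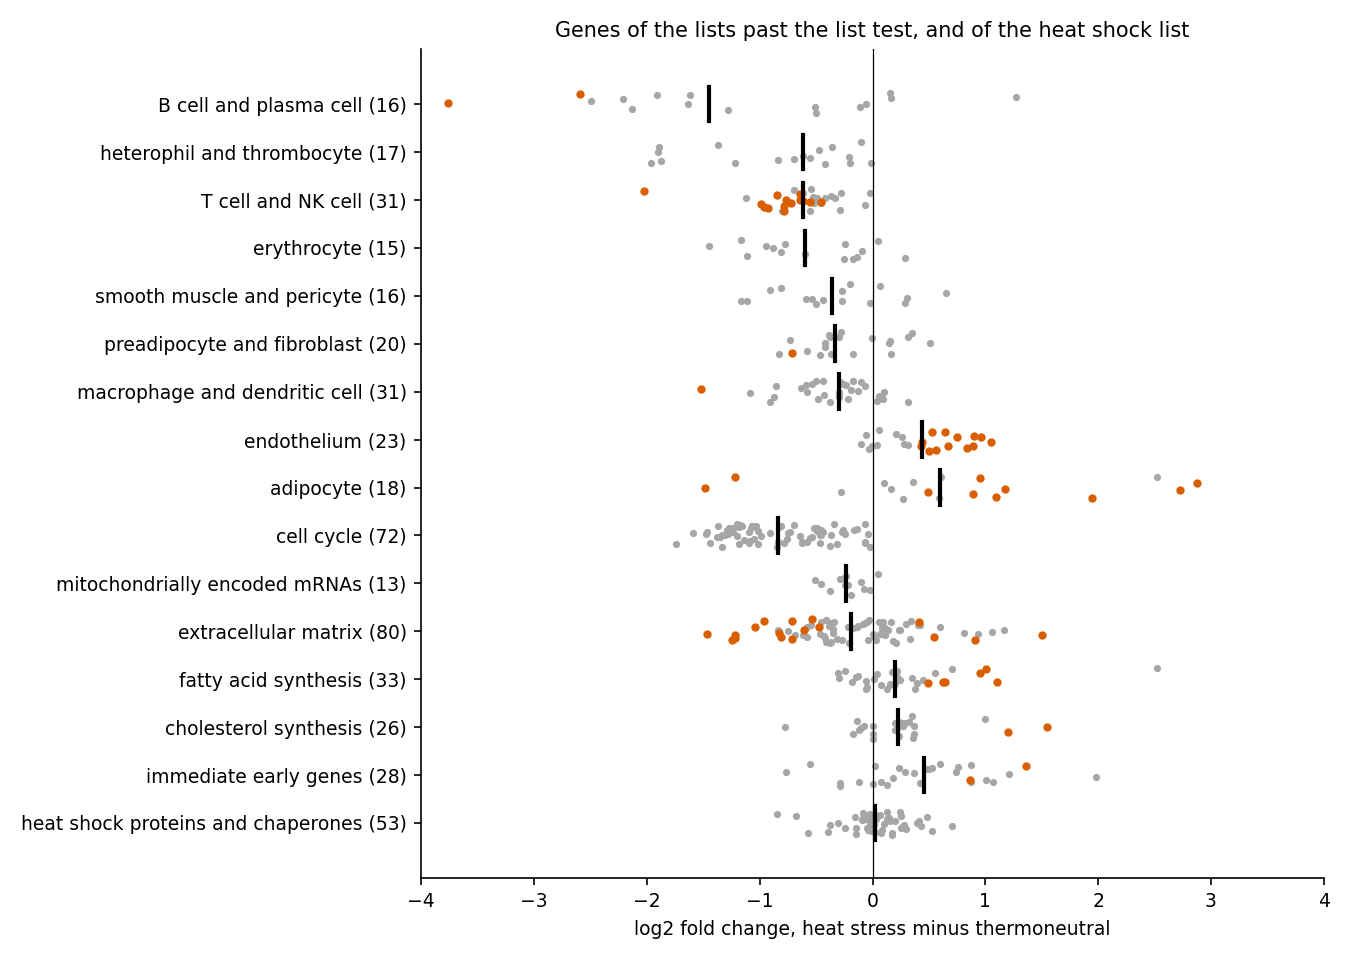
Each dot is the log2 fold change (x axis, heat stress minus thermoneutral) of 1 gene of a list fixed beforehand, with the number of genes measured in brackets; black bars are list medians. Orange dots passed at FDR 0.05 adjusted over the list alone. All 31 T cell and NK cell genes and all 72 cell cycle genes lie below 0, and the heat shock list centres on 0.02.

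Cell cycle genes were all lower: 72 of 72 measured had negative log2 fold changes, with a median of -0.84. In edgeR 0 passed adjusted over the list alone and 47 had an unadjusted p under 0.05, while 26 were lower at DESeq2's adjusted p under 0.05 over all genes. Camera gave adjusted p = 3.87e-17, against adjusted p = 0.88 with an estimated correlation. The mitotic genes RACGAP1 (7.42 ± 2.46 and 2.66 ± 0.61 CPM), CDC20 (7.12 ± 3.02 and 2.35 ± 0.52 CPM) and the condensin subunit SMC4 (53.2 ± 4.63 and 38.5 ± 2.51 CPM) had the smallest p. Thermoneutral 2 had the highest score (0.50, against -0.25 in each of thermoneutral 1 and 3 and -0.50 to -1.17 in heat stress).

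Smooth muscle and pericyte markers (16 measured, median -0.36) and erythrocyte markers (15 measured, median -0.60) passed camera downward (adjusted p = 0.0339 and 0.0106, and adjusted p = 0.56 for both with an estimated correlation). In edgeR 0 members of either passed adjusted over the list alone, and 7 and 3 had an unadjusted p under 0.05. DESeq2 called 2 smooth muscle genes, 1 higher and 1 lower, and 1 erythrocyte gene, which was lower. In smooth muscle, KCNMB1 and LMOD1 stood at log2 fold changes of -0.91 ± 0.29 and -0.27 ± 0.09 and RGS5 at 0.65 ± 0.19. The smooth muscle list score was -0.07 in heat stress 2 and -0.24 in thermoneutral 3, so the groups overlapped. Among erythrocyte genes, SPTB, HBA1 and HBBA stood at -1.11 ± 0.31, -0.88 ± 0.33 and -0.94 ± 0.36, and without thermoneutral 2 at -0.83, -0.44 and -0.49. Smooth muscle no longer passed without thermoneutral 1, thermoneutral 2 or heat stress 1 (adjusted p = 0.121, 0.232 and 0.226), nor erythrocytes without thermoneutral 2 or heat stress 1 (0.109 and 0.0651). Without heat stress 1 the voom medians were -0.19 and -0.28, against -0.38 and -0.54 with all libraries, and for erythrocytes -0.31 without thermoneutral 2. With HBBA, a haemoglobin gene, as a covariate, a setting chosen after seeing the data, they turned to 0.06 and 0.04 (adjusted p = 0.472 and 0.836). HBBA is itself in the erythrocyte list, so the move of that list was largely built in. Its level did not overlap between the groups, so this covariate cannot separate blood from treatment in any list. Marker lists of mesothelium, liver, peripheral nerve, skeletal muscle, and pancreas and intestine did not pass (adjusted p = 0.126, 0.345, 0.345, 0.551 and 0.345). Mesothelium passed downward without thermoneutral 1 or heat stress 2 and with the library number as a block (adjusted p = 0.0021, 0.00877 and 3.99e-05), and liver upward without heat stress 1 (0.0488). With the HBBA covariate mesothelium turned and passed upward, as did liver and peripheral nerve. Pancreatic enzyme mRNAs stood apart in 1 library: amylase AMY2A was at 2032 CPM in thermoneutral 2 and at 0.26 to 22.9 CPM in the other 5, and the elastases CELA2A and CELA3B were at 327 and 190 CPM there against at most 1.37 and 1.30 CPM elsewhere.

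**Figure D3:**
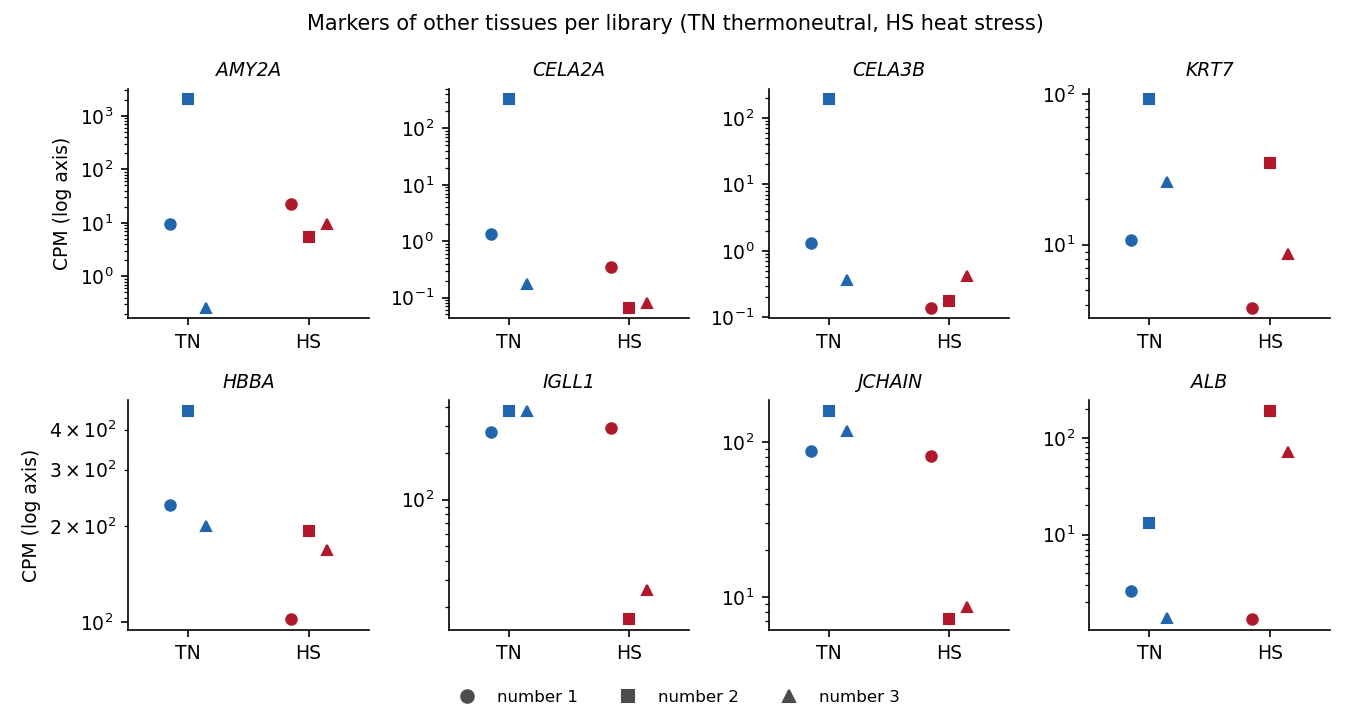
CPM (log axis) of 8 genes typical of other tissues and cells in the 3 thermoneutral (TN, blue) and 3 heat stress (HS, red) libraries, where circles, squares and triangles are replicates 1, 2 and 3. Pancreatic AMY2A, CELA2A and CELA3B and the epithelial keratin KRT7 peak in thermoneutral 2 (AMY2A 2032 CPM), IGLL1 and JCHAIN are low in heat stress 2 and 3, and ALB is high there (190 and 71.3 CPM).

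Heat shock proteins and chaperones did not differ as a list: 0 of 53 measured passed adjusted over the list alone in edgeR (8 had an unadjusted p under 0.05), with a median of 0.02 and adjusted p = 0.711. DESeq2 called 4 of them, 2 higher and 2 lower. In edgeR, HSPA8, the constitutive HSP70, averaged 1189 ± 221 and 1122 ± 86.9 CPM (FDR = 0.82), and HSP90AA1 1075 ± 180 and 1058 ± 153 CPM (FDR = 0.957). HSPH1 averaged 33.5 ± 2.36 and 35.5 ± 4.81 CPM, and HSPA2, another HSP70, 1050 ± 414 and 1712 ± 453 CPM (FDR = 0.286). The smallest p values belonged to HSP90AB1 (42.9 ± 2.29 and 28.9 ± 3.35 CPM, FDR = 0.0697), CDC37 and the endoplasmic reticulum chaperone HSPA5 (475 ± 98.4 and 297 ± 47.6 CPM, FDR = 0.118). CIRBP, the cold-inducible RNA-binding protein, was at 889 ± 11.8 and 937 ± 20.4 CPM (FDR = 0.705). Of its list of 18 temperature-responsive RNA-binding proteins, 1 rose adjusted over the list alone (YBX3, 1.41-fold), CLK1 and SRSF7 did not, and the list did not pass (adjusted p = 0.926).

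Immediate early genes passed upward (28 measured, median 0.45, adjusted p = 0.00535, and adjusted p = 0.94 with an estimated correlation). Their list score was 0.07 in heat stress 1 and 0.40 in thermoneutral 1, so the groups overlapped. DUSP1 (1.82-fold) and EGR3 (2.56-fold) rose adjusted over the list alone, and MCL1 averaged 278 ± 64.7 and 558 ± 219 CPM. Without thermoneutral 3 or heat stress 3 the list did not pass (adjusted p = 0.0506 and 0.101, voom medians 0.28 and 0.43 against 0.45). Mitochondrially encoded mRNAs passed downward (13 measured, median -0.23, adjusted p = 0.00367, and adjusted p = 0.94 with an estimated correlation), but with the haemoglobin gene HBBA as a covariate, a setting chosen after seeing the data, the adjusted p was 0.197 and the voom median -0.15, against -0.23 without it. In edgeR 0 passed adjusted over the list alone (3 at an unadjusted p under 0.05, 3 in DESeq2), with COX1 at -0.51 ± 0.17, COX3 at -0.38 ± 0.14 and ND6 at -0.46 ± 0.18. The mitochondrial list score was -0.12 in heat stress 3 and -0.14 in thermoneutral 3, so the groups overlapped. Nuclear genes of oxidative phosphorylation did not pass (71 measured, median -0.02, adjusted p = 0.71, with COX4I1, COX7A2 and COX5A at -0.37, -0.46 and -0.40). They passed downward without thermoneutral 2 (voom median -0.09, adjusted p = 0.00579) and with the HBBA covariate (-0.13, adjusted p = 2.58e-05). Since HBBA did not overlap between the groups, fits with this covariate cannot separate blood from treatment.

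Insulin and IGF signalling moved both ways, with 5 risers and 5 fallers of 34 adjusted over the list alone (adjusted p = 0.925 as a list). IGFBP2, an IGF carrier, rose 7.07-fold from 12.9 ± 6.62 to 90.9 ± 18.7 CPM, RPTOR rose 1.27-fold, and EIF4EBP1, a brake on translation, fell 1.36-fold. In the thyroid and glucocorticoid list (22 measured, adjusted p = 0.809), 3 rose and 1 fell adjusted over the list alone: FKBP5, a glucocorticoid-induced cochaperone, fell 2.36-fold, while TTR rose from 0.30 ± 0.24 to 3.46 ± 2.31 CPM. TTR is also in the liver list, and like ALB it was highest in heat stress 2 and 3 (5.85 and 3.30 CPM) and, among thermoneutral libraries, in thermoneutral 2 (0.57 CPM). Fatty acid oxidation had 4 risers, among them the peroxisomal PHYH (1.52-fold), ACOX2 (2.74-fold) and PECR (1.40-fold), and 1 faller of 44 in that count (adjusted p = 0.554). Thermogenesis and calcium cycling had 2 risers, SLC6A8 (2.33-fold) and PRDM16 (1.98-fold), and 1 faller, SLC25A6 (1.45-fold), of 26 (adjusted p = 0.711), and UCP3 was at 0.37 ± 0.12 and 0.38 ± 0.18 CPM. In glycolysis (38 measured, adjusted p = 0.777), SLC16A1 rose 1.54-fold and ENO1 fell 1.38-fold.

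Antioxidant genes had 2 risers, SEPW1 (1.47-fold) and NFE2L1 (1.64-fold), and 2 fallers, one of them the secreted superoxide dismutase SOD3 (2.08-fold), of 55 adjusted over the list alone (adjusted p = 0.777). Adipokines and their receptors had CDH13 (1.60-fold) and APLNR up and ANGPTL2 (1.65-fold) and C1QTNF7 (-0.73) down of 27 (adjusted p = 0.943). Inflammatory genes had NFKBIA up (1.79-fold) and IL15 down (1.61-fold) of 57, with IL16 at -0.40 (adjusted p = 0.777), and the clock list had CRY2 up (1.94-fold) of 26, with CSNK1E and CIPC at 0.30 and 0.35 (adjusted p = 0.777). As in other lists above, 0 members passed adjusted over the list alone in edgeR in 4 further lists, while 9, 10, 4 and 11 had an unadjusted p under 0.05. These were the interferon response (44 measured, adjusted p = 0.11), adipogenic regulators (54, 0.554), autophagy and lysosome (43, 0.926), and the unfolded protein and integrated stress response (50, 0.711). Their leading members in edgeR were OASL (1.28 ± 0.24), CMPK2 and HERC3, then KLF15 (0.80 ± 0.18), RUNX1T1 and TGFB2, then ATG9A (0.29 ± 0.07), ATG4B and SQSTM1, and for the last list VLDLR, HSPA5 and LOC100858796 (0.60 ± 0.17). DESeq2 called 6, 4, 2 and 6 genes in these 4 lists over all genes. The interferon response passed upward without thermoneutral 3 or heat stress 3 (adjusted p = 0.0148 and 0.00483), and adipogenic regulators without heat stress 1 (0.00377). Median, mean and camera direction differed in sign for 6 lists: stress response, fatty acid uptake, clock, insulin, autophagy and adipokines.

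**Figure D4:**
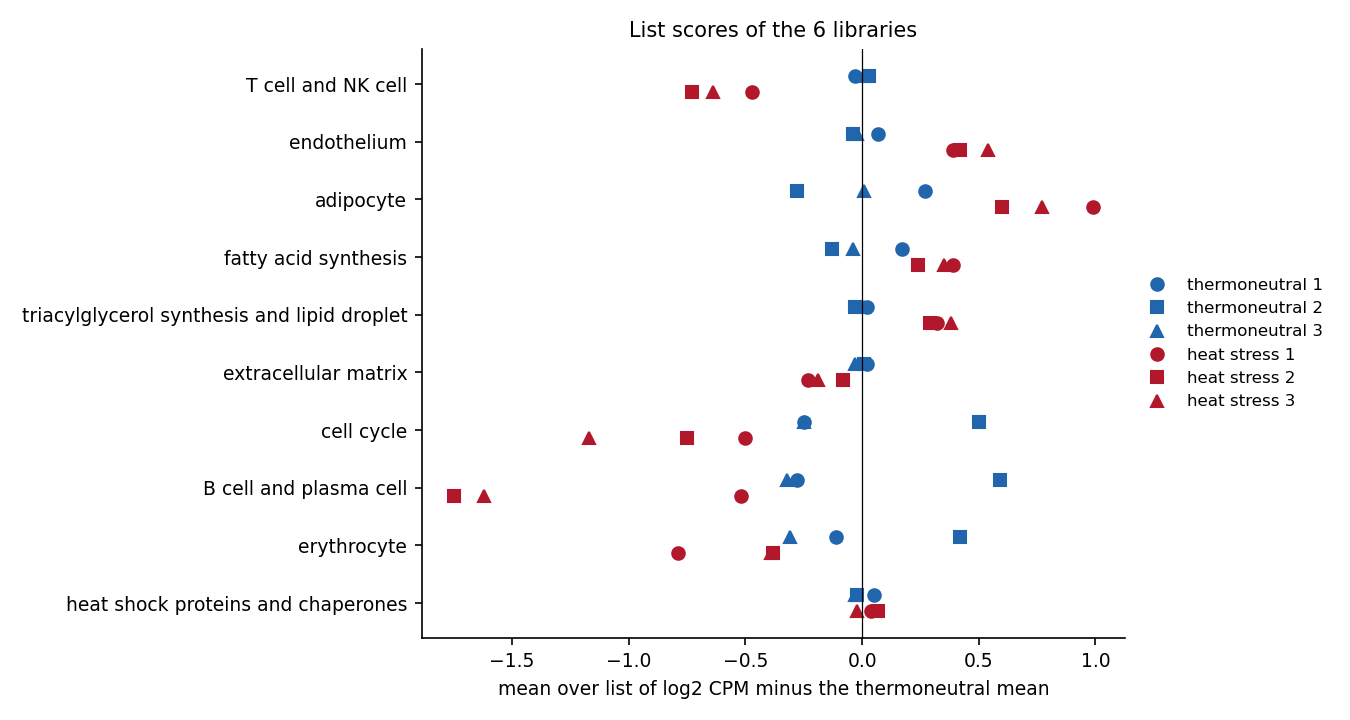
Mean over the genes of a list of log2 CPM minus the thermoneutral mean (x axis) for 10 lists (y axis), 1 symbol per library (blue thermoneutral, red heat stress). The scores of every list but heat shock separate the groups, widely for T cells (-0.03 to 0.03 against -0.73 to -0.47). The gap is narrow for erythrocyte genes (-0.31 in thermoneutral 3, -0.38 in heat stress 2). Thermoneutral 2 lies apart for cell cycle, B cell and erythrocyte genes.

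At a 2-fold change and an unadjusted p under 0.05, a threshold without control for multiple testing, 693 genes differed in edgeR, 361 higher and 332 lower. The side with more genes varied: it was 335 higher and 360 lower with upper quartile scaling, 385 and 391 with no filter, 298 and 371 without thermoneutral 3, and 330 and 363 without heat stress 1. The authors' deposited table lists 742 genes at that threshold, 374 higher and 368 lower, and holds 16 of the 26 genes above. With the authors' deposited adjusted p under 0.05 there are 1364 genes, 756 higher and 608 lower, which include all 26. The authors' deposited table of gene ontology terms has 142 terms at an adjusted p under 0.05. Chromosome segregation has 22 of the listed genes in that table, 0 up and 22 down, extracellular matrix has 24, 12 up and 12 down, triglyceride metabolic process has 11, 8 up and 3 down, and T cell differentiation has 16, 6 up and 10 down. Those genes were chosen on these same libraries, so the terms are not independent evidence of a direction. On the authors' FPKM values, limma gave 205 genes at the same threshold, 145 higher and 60 lower, and on TPM 322, 233 higher and 89 lower.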

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

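Thinned counts and the haemoglobin covariate were chosen after seeing the data; the other settings were planned. The count of 26 genes became 1352 with DESeq2, 307 with limma-voom and library weights, 99 with library totals in place of TMM, 133 with a filter of 1 CPM in all 6 libraries, 120 and 118 on log2(FPKM + 1) and log2(FPKM + 0.1), and 250 and 256 on log2(TPM + 1) and log2(TPM + 0.1). It was 22 to 27 with limma-voom, DESeq2 size factors, upper quartile scaling, robust edgeR and the other filters, 18 after thinning, and 3 (without thermoneutral 3, or without heat stress 3) to 35 (without heat stress 1) with 1 library left out. All 26 kept their direction in each of these fits, and the 26 past the FDR remained so in DESeq2 and 18 of them after thinning, against 2 to 15 with 1 library left out. Their groups did not overlap in value, so a kept direction with 1 library left out was largely set beforehand. The 693 genes at 2-fold became 351 with the 1 CPM filter, 205 and 343 on FPKM with pseudocounts of 1 and 0.1, and 322 on TPM + 1. A pseudocount shrinks the folds of low genes and the 1 CPM filter tests fewer genes; for the remaining differences the cause was not tested.

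Deviations of same-numbered libraries correlated at 0.08, 0.25 and 0.04, and 3 of 6 libraries correlated best with their own number. So few libraries cannot tell whether the numbers pair them. With the number as a replicate block 95 genes passed, 74 higher and 21 lower, 17 of the 26 among them, and 6 process and 10 cell type lists passed.

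Of the 6 process and 9 cell type lists past camera, 0 and 0 held with an estimated correlation, and fry passed 1 process list and 2 cell type lists; the estimated correlations and fry's different question are built into those settings. With 1 library left out, 6 to 8 process lists and 6 to 10 cell type lists passed. With haemoglobin HBBA as a covariate, the medians of smooth muscle, erythrocyte and heterophil genes turned to 0.0606, 0.0398 and 0.334. HBBA is itself an erythrocyte marker, so the erythrocyte move was largely built in, and for the other lists the cause was not tested. Its level did not overlap between the groups, so this setting cannot separate blood from treatment. In that setting the adipogenic, oxidative phosphorylation, mesothelium, liver and peripheral nerve lists passed (adjusted p = 0.0344, 2.58e-05, 0.0062, 0.000792 and 0.0128), oxidative phosphorylation downward and the others upward. Macrophage genes moved to -0.559 and adipocyte genes to 0.337. The 19 named genes past the FDR gave 209 pairs of a gene and a setting, of which 0 changed sign and 92 were weaker. These genes were named for groups that do not overlap, so a kept sign was largely set beforehand. Among the other named genes, UCP3 was at -0.0102 in limma-voom, and with 1 library left out ranged from -0.371 to 0.340, HSPA8 from -0.199 to 0.0727, HSP90AA1 from -0.117 to 0.125 and ADIPOQ from -0.0891 to 0.230, all far from the threshold, and the cause was not tested. Depth limits genes near the floor such as UCP3, at about 0.37 CPM.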

Other observations

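IGLL1 and JCHAIN, 2 antibody genes, differed within the heat stress group. The immunoglobulin light chain gene IGLL1 stood at 277, 380 and 377 CPM in the thermoneutral libraries and 293 CPM in heat stress 1, but at 16.6 and 25.6 CPM in heat stress 2 and 3. JCHAIN, the joining chain of secreted antibodies, had 87.8, 159 and 118 CPM in thermoneutral fat, 81.3 CPM in heat stress 1 and 7.17 and 8.55 CPM in heat stress 2 and 3. The heavy chain gene IGHVL did not split this way (19.99, 16.6 and 16.7 CPM in heat stress). In the same 2 libraries the liver mRNA of albumin, ALB, was highest, at 190 and 71.3 CPM against 1.33 to 13.1 CPM in the other 4. Thermoneutral 2, the library with pancreatic enzymes, also led in the epithelial genes KRT19 (61.4 CPM) and EPCAM (18.5 CPM) and in the pancreatic granule gene SYCN (168 CPM against at most 1.40 CPM). PLIN5, a droplet coat protein of oxidising tissues, averaged 9.21 ± 4.001 and 55.8 ± 17.7 CPM and missed the threshold (edgeR FDR = 0.0518). These genes were picked after their values were seen.

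The tests of thermoneutral 2 and of adipocyte share below were chosen after their results were seen. T cell and NK cell mRNAs were lower in all 3 heat stress libraries (camera adjusted p = 1.29e-11, and adjusted p = 0.077 with an estimated correlation). If thermoneutral 2, which carries pancreatic and extra blood mRNA, made the difference, the list median would near 0 without it, but it stayed at -0.62. Thinning to equal depth left it at -0.60, but thinning keeps the expected ratios between groups. Here and below it could therefore show only an effect of low counts. With HBBA as a covariate the T cell median was -0.72. HBBA differed between the groups without overlap, so here and below this covariate cannot separate blood from treatment. HBBA is also an erythrocyte marker, so the erythrocyte median of 0.04 in that fit was largely set beforehand. Fewer T cells, or less of these mRNAs per cell, in the fat of heat-stressed chickens remains a hypothesis that may hold, and mRNA levels do not separate the 2. A difference in lymphoid tissue taken with the fat was not tested and stays open.

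Cell cycle mRNAs were lower in heat stress (camera adjusted p = 3.87e-17, and adjusted p = 0.88 with an estimated correlation). Without thermoneutral 2 the median shrank from -0.84 to -0.57, so that library carries part of the size but not the whole. Thinning gave -0.89 and the HBBA covariate -0.53. Less proliferation in heat-stressed fat is one open reading; the genes move together so strongly (estimated correlation 0.68) that they may amount to few independent observations. Whether the dividing cells were immune cells or fat cell precursors was not tested.

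The fatty acid synthesis list was higher in heat stress by camera (adjusted p = 0.00127), but not with an estimated correlation (adjusted p = 0.59) or in fry (adjusted p = 0.0837), and the triacylglycerol list did not pass camera (adjusted p = 0.11). A larger share of adipocytes would raise adipocyte markers alike, but 2 of them (PNPLA2 and LPIN1) fell adjusted over the list alone while 8 rose. Of these 2, LPIN1 also fell adjusted over the triacylglycerol list, while PNPLA2 did not pass over the lipolysis list or over all genes (FDR = 0.144). All 18 markers are also in a process list, so they cannot separate share from regulation within cells, and the question of share stays open. Without heat stress 1, the library with the highest SCD and DGAT2, the fatty acid synthesis median was 0.24, after thinning 0.18, and without thermoneutral 2 it shrank from 0.19 to 0.13. With the HBBA covariate it was 0.12. A shift of heat-stressed fat towards making and storing lipid is a hypothesis, since lower PNPLA2 and FKBP5 beside higher FASN and LPL may equally mark a different feeding state at sampling. The time since the last meal is not given in the sources used here, so that reading stays open.

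The 6 libraries split 3 against 3 in 10 ways, too few for a share under 0.05. For genes at the FDR the real split gave 26 and the highest other 1, and 1 of the 10 splits gave as many. For genes at 2-fold the values were 693 and 314, with 1 of 10 splits as large. For process lists they were 6 and 6, and for cell type lists 9 and 9, with 2 of 10 splits as large in each case. Splits that mixed the groups passed 3 to 6 process lists and 1 to 9 cell type lists. Passing camera at the preset correlation was therefore not particular to the real grouping. In DESeq2 the real split gave 1364 genes and the highest other 104.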
